A study of Homo sapiens with 8 samples.

How the data were processed

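RNA from 8 libraries of RMG1, an established human ovarian clear cell carcinoma line, was analysed in 4 groups of 2: cells with ARID1A (wild type), cells with ARID1A knocked out, cells carrying a control shRNA, and cells in which CAPH2 was knocked down. CAPH2 is a protein name for the product of NCAPH2, a subunit of condensin II. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase and made into libraries with the TruSeq Total RNA kit. Nothing in the labels says whether libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

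The authors deposited 1 table of expected counts per Ensembl gene, with 1 column per library and no pooling of replicates. Per the submitters' processing notes, Bowtie2 (version not given in the sources used here) and RSEM 1.2.12 were used with the hg19 build, and the annotation release and the strand setting are not given in the sources used here. The deposited expected counts were whole numbers already, so rounding them changed no value. RSEM shares reads that match several genes among them, so values of near-identical copies, overlapping genes and antisense partners are uncertain for single genes. The table holds 57736 IDs, of which 29952 had a count above 0 in at least 1 library. Gene names came from a table of Ensembl IDs and, for 4835 further IDs, from GENCODE 29, which gave 28427 of the counted IDs a symbol and left 1525 without. IDs without a symbol took 12.5% to 16.1% of the counts of a library, and the 3 IDs with the highest counts took 15.3% to 19.3%. The reference genome at hand was GRCh38, which differs from hg19, so no coordinates are given; GENCODE 29 on GRCh38 was used for names, chromosomes, neighbour order, GC content and transcript length.

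A single count was worth 0.0261 to 0.0413 CPM, the count scaled by library size. Where both libraries of a group held 0 counts, the fold is given as a lower bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its exact 95% counting interval. Such intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

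Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 16657 genes, and libraries were scaled with trimmed means of M values (TMM). A quasi-likelihood F-test with group means and no block was fitted to all 8 libraries together, because 2 libraries per group leave few residual degrees of freedom in a fit of a single comparison. The fit had 4 residual degrees of freedom and a common biological coefficient of variation of 7.74%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. The contrasts were knockout minus wild type, knockdown minus shRNA control, the difference between those effects, and shRNA control minus wild type. Overlaps of calls were tested per direction with a one-sided Fisher's exact test across genes. Levels are CPM after TMM scaling, given as mean ± SD over 2 libraries, and fold changes are log2 values with the standard error (SE) of the fit.

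Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated per list. There were 27 lists: SWI/SNF subunits, condensin and cohesin subunits and loaders, G1/S and DNA replication, mitosis and spindle checkpoint, replication-dependent histones, p53 targets, type I interferon response, NF-kB and inflammatory cytokines, antigen presentation, immediate early genes, epithelial junctions and keratins, mesenchymal transition, collagens and matrix, YAP and TGF-beta targets, ovarian clear cell markers, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and amino acid stress, oxidative stress (NRF2 targets), polycomb subunits, genes reported as ARID1A-dependent in cancer cells, DNA repair, cytosolic ribosomal proteins (a check of RNA composition), mitochondrial transcripts, and markers of fibroblasts, leukocytes and endothelium. Of the list genes, 21 had no ID match. The mitochondrial list (0 of 13 genes matched) and the endothelial list (2 genes tested) had fewer than 3 tested members and were left out, so 25 lists were tested.

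The groups, designs, lists, most alternative settings and the rule for named genes were fixed before the data were examined. The rule took ARID1A and NCAPH2; per main comparison, among changed genes with a symbol, a mean of at least 1 CPM and no overlap between the libraries of both groups, the 6 largest rises and the 6 largest falls; for the 8 biology lists with the highest share of changed members and for the SWI/SNF and condensin lists, the 2 strongest members in the more frequent direction and 1 in the other; among genes changed by both perturbations, 5 rising in both, 5 falling in both and 3 of each opposite kind; and for the difference between effects, the 3 smallest p-values in each direction. The largest falls with small noncoding RNAs and pseudogenes passed over were chosen after their values had been seen. Other genes, 37 gene families, windows of 40 neighbouring genes and runs of neighbouring changed genes were also chosen after values had been seen. A mitotic and an interferon-related gene looked at in this way were left unnamed after their calls were lost on leaving out 1 library, while UBE2C, whose knockdown call was lost in the same way, is named with its losses.

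The steps were tested on simulated data made from the means and library sizes of the real genes, with 200 genes changed. For the knockout comparison, 38 of 67 genes changed 1.5-fold, 47 of 65 changed 2-fold and 57 of 65 changed 4-fold were recovered, and 12 of 15941 unchanged genes were called. For the knockdown comparison these were 35 of 66, 45 of 66 and 53 of 65, with 14 of 15938 unchanged genes called. A raised list was found with both kinds of correlation, and 0 of 23 unchanged lists were called in either simulation. Simulated genes were drawn independently of each other, with a spread set by a single trend on expression for all groups. Real genes may correlate and real groups may differ in spread, so these rates do not carry over to the real calls. Replicates were compared by a chi-square test of their counts, and no pair was identical or within sampling noise.

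Alternatives were DESeq2's size factors (the RLE option of edgeR), scaling without the 50 genes with the highest counts, the Wald test of DESeq2 1.42.0, no filter beyond a count above 0, a filter of at least 1 CPM in at least 4 libraries, a fit of only the 4 libraries of a comparison, the replicate number as a block, leaving out each library in turn, a 2-fold threshold, and for lists an estimated correlation and a prior count of 0.5. Counts outside shifted windows of neighbouring genes, and fold changes minus the median of such a window, were added after the data had been seen. Same-numbered libraries of different groups did not deviate together from their group means, with correlations from −0.024 to 0.030 across genes, so the numbers were not taken to pair the samples.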

Results

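Total RNA of RMG1 cells was sequenced in 4 groups of 2: wild-type cells, ARID1A-knockout cells, cells with a control shRNA and cells with a knockdown of CAPH2 (gene NCAPH2). RMG1 is a line of ovarian clear cell carcinoma. ARID1A is a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, and NCAPH2 encodes a subunit of condensin II, which compacts chromosomes. Total counts per library were 24559547 and 27144974 (wild type), 35392307 and 37378691 (knockout), 32831617 and 36731763 (shRNA control) and 31791100 and 31562201 (knockdown). Correlations of log2 CPM between the libraries of a group lay between 0.981 and 0.987. Chi-square per degree of freedom was 20.5 for the wild-type pair, 5.53 for the knockout, 4.42 for the shRNA control and 15.1 for the knockdown. The first principal component held 42.7% of the variance and set the knockout libraries apart from the others. The second held 22.2%, with the wild-type libraries at one end and the knockdown libraries at the other.

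The targeted genes were examined first. ARID1A (ENSG00000117713, chromosome 1) stood at 10.4 ± 2.33 CPM in wild-type cells and 6.14 ± 0.739 CPM in knockout cells (mean ± SD, n = 2 each). NCAPH2 (ENSG00000025770, chromosome 22) stood at 24.9 ± 1.24 CPM in shRNA control cells and 8.86 ± 0.174 CPM in knockdown cells. ARID1A fell in the knockout (log2 fold change −0.77, SE 0.16, adjusted p = 0.00274) and NCAPH2 fell in the knockdown (−1.49, SE 0.10, adjusted p = 1.84e-06; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). ARID1A was at 9.78 ± 0.130 CPM in shRNA control and 9.09 ± 0.0999 CPM in knockdown cells, which did not pass the test (−0.11, edgeR adjusted p = 0.717). NCAPH2 also fell in the ARID1A knockout, from 28.4 ± 2.27 to 22.4 ± 2.05 CPM (−0.34, SE 0.09, edgeR adjusted p = 0.0144), a call lost without wild-type library 2 (−0.26) or knockout library 1 (−0.25). Neighbours on the chromosome were lower too in the knockout: the median over 40 neighbours of ARID1A was −0.25, with 80% of them lower, and that over 22 neighbours of NCAPH2 was −0.24, with 81.8% lower. ARID1A lay in a window of neighbouring genes with a median of −0.34, and its fold change minus that median was −0.44.

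**Figure D1:**
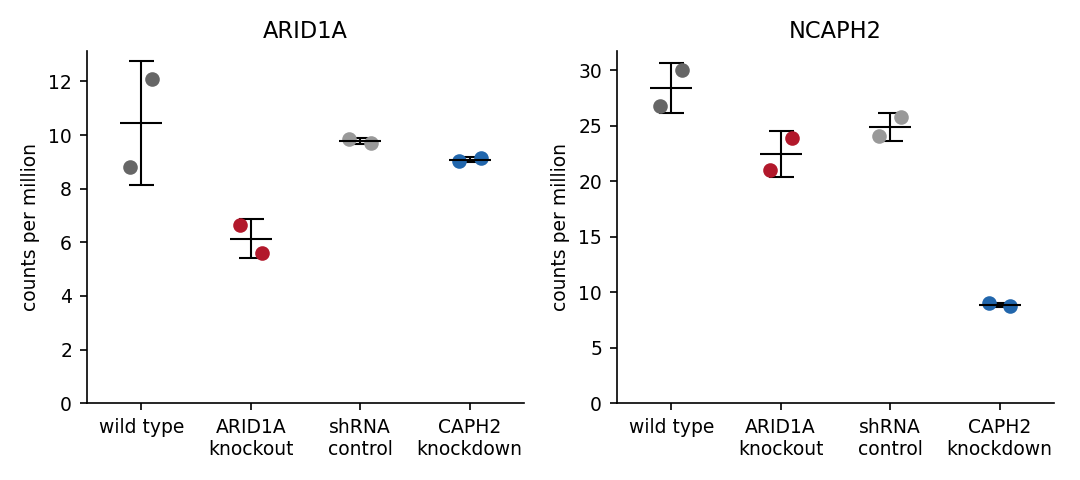
Level of ARID1A (left) and NCAPH2 (right) in CPM on linear axes that start at 0, for wild type, ARID1A knockout, shRNA control and CAPH2 knockdown; dots are single libraries, and bars are the mean ± SD of 2 libraries. ARID1A is lowest in the knockout (6.14 CPM) and NCAPH2 is lowest in the knockdown (8.86 CPM).

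The comparison of ARID1A-knockout with wild-type cells asked which transcripts depend on ARID1A. Genes that were silent or nearly so in wild-type cells came up in the knockout: LAMA4, a laminin chain, rose from 0.0207 ± 0.0292 to 29.8 ± 0.243 CPM, and CDH2, the neuronal cadherin, from 0.0207 ± 0.0292 to 7.31 ± 0.336 CPM. CXCL1, a chemokine gene, rose from 1.83 ± 0.0202 to 22.5 ± 0.0330 CPM, while CDH6, a cadherin of kidney and ovarian tumours, fell from 257.8 ± 0.621 to 5.61 ± 0.376 CPM (log2 fold change −5.52, SE 0.07). In all, 5751 of 16657 genes changed, 2794 up and 2957 down, of which 1667 changed at least 2-fold (852 up, 815 down). Among 12930 protein-coding genes, 2535 rose and 2650 fell. The test was edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05 and n = 2 per group.

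Of the largest rises, C2orf80 went from 0 to 7.52 ± 1.84 CPM (at least 130.5-fold higher) and PRSS35, a secreted protease relative, from 0 to 5.65 ± 0.166 CPM (at least 97.7-fold higher). SRGN, the proteoglycan serglycin, went from 0 to 4.48 ± 0.172 CPM (at least 77.4-fold higher). With 1 count in the wild type, the ratio was 1543 for LAMA4 (counting interval 276.6 to 60970), 379 for CDH2 (67.7 to 15000) and 328 for LGALS1, or galectin-1 (58.7 to 13000). The largest falls by the fixed rule were 6 copies of U6 small nuclear RNA, RNU6-5P, RNU6-3P, RNU6-2, RNU6-9, RNU6-4P and RNU6-6P, each at 3.33 ± 0.256 CPM in wild-type and 0 in knockout libraries (at least 82.8-fold lower). These copies are nearly identical in sequence, so their single values are uncertain. RNU6-1 rose to 26.3 CPM in the same libraries. The calls of RNU6-4P and RNU6-6P were lost on leaving out any 1 of the wild-type or knockout libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p 0.0563 to 0.174), and that of RNU6-6P also with a replicate block (0.0529).

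Falls of other genes, named after their values were seen, included LYPD1, from 1.84 ± 0.199 CPM to 0 (at least 45.7-fold lower), and PDE10A, a cyclic nucleotide phosphodiesterase, from 7.38 ± 1.32 to 0.0274 ± 0.0388 CPM (wild-type to knockout ratio 273.5, counting interval 75.2 to 2267). TDRD9, an RNA helicase of the piRNA pathway, fell from 19.3 ± 0.166 to 0.364 ± 0.145 CPM (−5.72, SE 0.26). The kinase gene PAK3 fell from 5.87 ± 1.18 to 0.0522 ± 0.0739 CPM (−6.68, SE 0.72), and its fitted value was −10.52 without knockout library 2, which held its only knockout counts. PAK3 was also low in shRNA control cells (0.271 ± 0.209 CPM). ZNF737 and FGB, the fibrinogen beta chain, each had a ratio of 54.9 (14.7 to 461). Knockout library 2 held the only knockout counts of ZNF737, which without it stood at 0.

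The list of NF-kB and inflammatory cytokine genes rose in the knockout, with 14 of 19 tested members up and 1 down, both over all genes and adjusted over the list alone (camera adjusted p = 0.00029). Its adjusted p = 0.222 with an estimated correlation, the highest of 12 alternatives that ranged from 1.57e-05. CXCL1 (log2 fold change 3.62, SE 0.14), CXCL2 (3.29, SE 0.23) and CXCL8 (2.55, SE 0.15), which attract neutrophils, rose together with BIRC3, an inhibitor of apoptosis (2.17, SE 0.09), TNF (1.69, SE 0.21) and NFKBIA, the inhibitor of NF-kB (0.99, SE 0.12). TNFAIP2 was the member that fell (−1.07, SE 0.07). It lies in a window of neighbours with a median of −0.65, and BIRC3 in one of −0.58.

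Ovarian clear cell markers fell: 9 of 14 tested members were lower and 1 was higher, over all genes and adjusted over the list alone (camera adjusted p = 0.00179). Its adjusted p = 0.254 with an estimated correlation, within a range of 3.94e-05 to 0.254 over 12 alternatives. After CDH6, the falls were led by FXYD2, a subunit that modulates the sodium pump (−2.60, SE 0.09; −1.88 after subtraction of its window's median), GLRX, a glutaredoxin (−2.01, SE 0.09), and SPP1, or osteopontin (1828 ± 175 to 814.6 ± 17.0 CPM). The arginase gene ARG2 rose (0.26, SE 0.07), a call lost without wild-type library 1 (0.16) or knockout library 2 (0.23).

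Several other lists held many changed genes that went both ways, and none of them passed the camera test. Among collagens and matrix genes, 7 rose and 7 fell of 17 (list alone, 7 and 7). COL4A1 (1.06, SE 0.06) and LAMB1 (1.05, SE 0.06) rose, and LAMB3, a chain of laminin-332, fell (−1.58, SE 0.07). Of NRF2 targets, 6 rose and 6 fell of 15 (list alone, 6 and 8). AKR1C1 (3.17, SE 0.13) and TXNRD1 (0.71, SE 0.05) rose. Of unfolded protein and amino acid stress genes, 5 rose and 10 fell of 20 (list alone, 6 and 10). The pseudokinase gene TRIB3 (−1.69, SE 0.07; −1.29 after subtraction of its window's median) and the serine synthesis gene PSAT1 (−1.35, SE 0.08) fell. SLC7A11, the cystine transporter, rose (1.08, SE 0.09). Of YAP and TGF-beta targets, 6 rose and 6 fell of 16 (list alone, 6 and 6). The receptor tyrosine kinase gene AXL (3.21, SE 0.30) and ANKRD1 (2.24, SE 0.21; window median −0.40) rose, and PMEPA1 fell (−2.88, SE 0.11).

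Genes reported as ARID1A-dependent in cancer cells had 5 rises and 4 falls among 13 (list alone, 5 and 4). ANXA1 rose (2.15, SE 0.06), and STAG1, a cohesin subunit, fell (−0.34, SE 0.06). In cholesterol synthesis, 4 rose and 9 fell of 20 (list alone, 4 and 9). MVK, the mevalonate kinase gene, fell (−0.69, SE 0.09), and INSIG1 rose (0.48, SE 0.07). SWI/SNF subunits had 6 rises and 6 falls among 26 (list alone, 6 and 6). SMARCA2, an ATPase of the complex, rose (0.77, SE 0.06), DPF3 fell (−2.76, SE 0.34) and ARID2 rose (0.46, SE 0.06). ARID2 lies in a window with a median of 0.56, and its value minus that median was −0.09. Condensin and cohesin genes had 4 rises and 7 falls among 25 (list alone, 4 and 7). WAPL, which releases cohesin, fell (−0.47, SE 0.06, and −0.18 after subtraction of its window's median). TOP2B, a topoisomerase on the list and not a subunit of either complex, rose (0.49, SE 0.05, and 0.20 after subtraction).

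Of mitotic and spindle checkpoint genes, 14 rose and 3 fell of 33 (list alone, 14 and 3), and the list did not pass (camera adjusted p = 0.174). UBE2C, which drives exit from mitosis, rose (0.68, SE 0.07), while the proliferation marker MKI67 fell from 379.5 ± 3.69 to 201.5 ± 13.7 CPM (−0.91, SE 0.06); its value was −0.22 after subtraction of its window's median. Of mesenchymal genes, 3 rose and 3 fell of 15 (list alone, 3 and 4). CDH2, VIM, the intermediate filament vimentin (3.09, SE 0.13), and ZEB1, a repressor of epithelial genes (2.66, SE 0.28), rose. FN1, or fibronectin, fell from 4061 ± 344 to 1116 ± 131.6 CPM. Epithelial junction and keratin genes had 3 rises and 8 falls among 21 (list alone, 3 and 8).

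The remaining lists did not pass in the knockout. Members up and down over all genes were 3 and 10 of 28 for G1/S and replication (list alone, 3 and 10), 1 and 3 of 16 for histones (0 and 3), 3 and 6 of 23 for p53 targets (3 and 8). They were 6 and 5 of 20 for interferon response (8 and 5), 5 and 2 of 12 for antigen presentation (6 and 2) and 4 and 4 of 19 for immediate early genes (5 and 4). Counts were 3 and 5 of 19 for hypoxia and glycolysis (4 and 5), 2 and 1 of 16 for polycomb subunits (1 and 0) and 5 and 4 of 20 for DNA repair (5 and 4). Ribosomal protein genes, a check of RNA composition, had 1 up and 11 down of 27 (1 and 12). Among markers of other cell types, fibroblast genes had 1 up and 2 down of 4 (1 and 2) and leukocyte genes 1 up and 2 down of 6 (1 and 2). The camera test, the median and the mean of the members differed in sign for the mesenchymal, collagen, NRF2, DNA repair and fibroblast lists. The sign of the hypoxia median also turned under both other scalings tried.

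Neighbouring genes shifted together along parts of several chromosomes in the knockout. Among 246 windows of up to 40 neighbouring genes with 9754 genes placed, 29 had a median beyond the bound of 0.26 from shuffled gene orders, 22 lower and 7 higher. The strongest stretches were C11orf54 to ST14 on chromosome 11 (median −0.56), EXD2 to MTA1 on chromosome 14 (−0.51), YARS2 to MFSD5 on chromosome 12 (0.49) and NBL1 to EYA3 on chromosome 1 (−0.41). No window passed in the knockdown (0 of 246, bound 0.17), and 10 passed between shRNA control and wild-type cells (2 lower and 8 higher, bound 0.20). Both lower ones (−0.23 and −0.21) lay in a lower stretch of the knockout on chromosome 10, MCU to MTG1 (−0.38). On chromosomes 11 and 18 the control shifts (0.21 and 0.24) overlapped knockout stretches of opposite sign. Both comparisons use the same wild-type libraries.

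**Figure D2:**
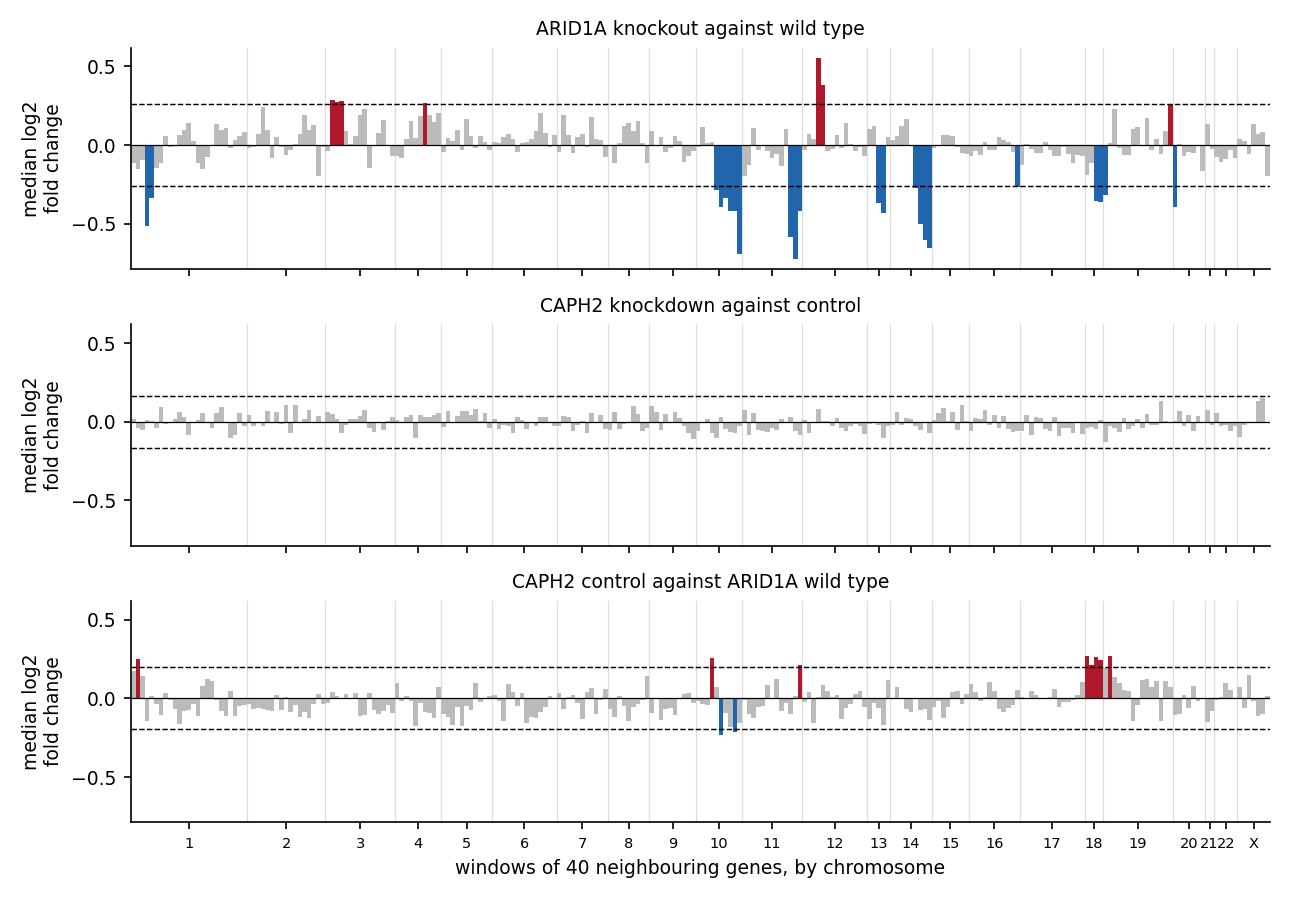
Median log2 fold change of windows of 40 neighbouring genes (bars, vertical axis) in order along the chromosomes (horizontal axis), for the knockout, the knockdown and shRNA control against wild-type cells; dashed lines are the bounds from shuffled gene orders. Coloured bars lie beyond them: 29 in the knockout, 0 in the knockdown and 10 between the control groups.

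**Figure D3:**
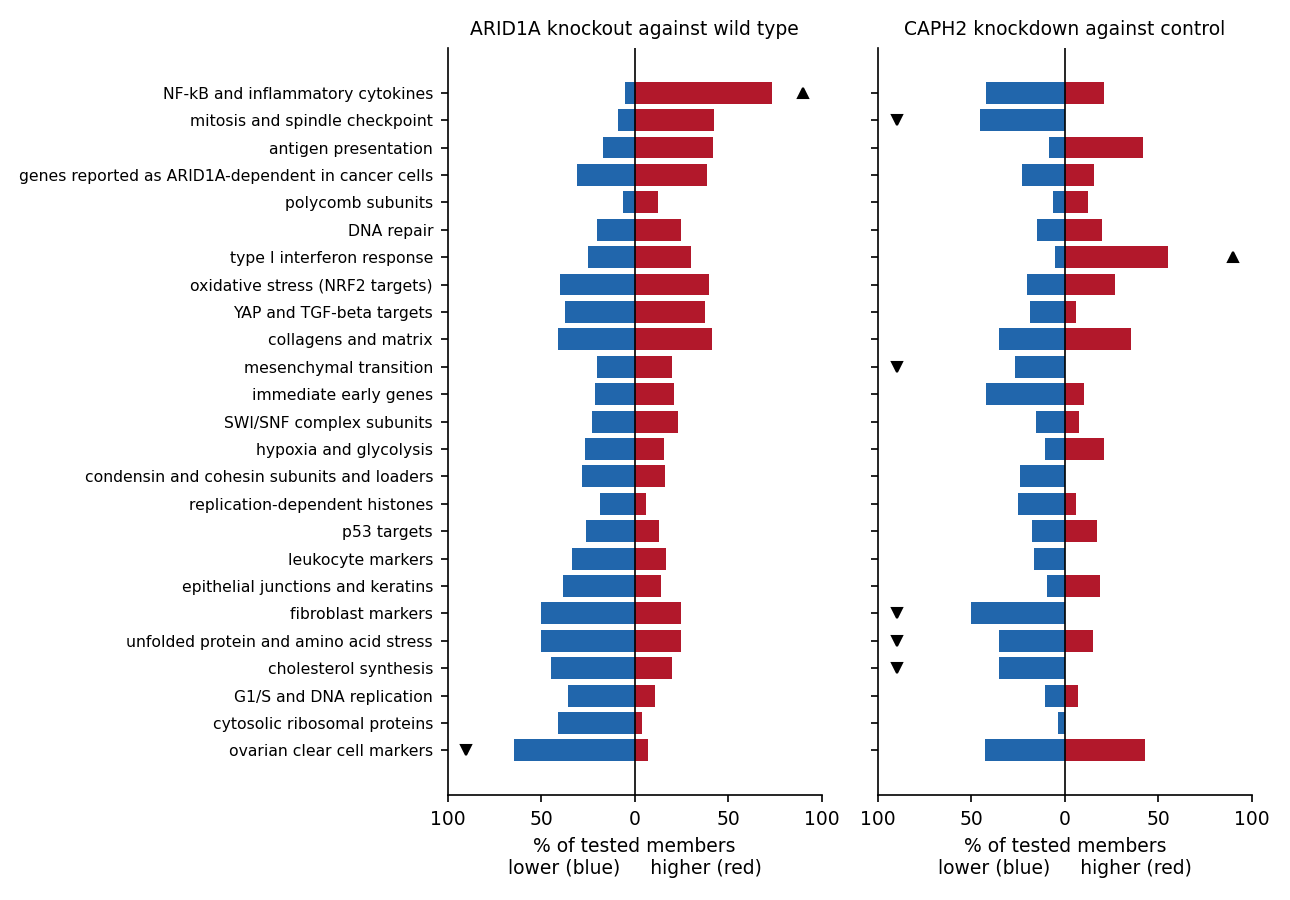
Share of the tested members of each of 25 gene lists that were higher (red, to the right) or lower (blue, to the left), in percent, in the ARID1A knockout (left panel) and in the CAPH2 knockdown (right panel); black triangles mark lists past the camera test and point in its direction. In the knockout the NF-kB list is up and the clear cell markers are down, and in the knockdown the interferon list is up and 5 lists are down, mitosis among them.

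The comparison of CAPH2-knockdown with shRNA control cells asked which transcripts depend on condensin II. CCR6, a chemokine receptor, had no count in the other groups and reached 25.9 ± 2.34 CPM in knockdown cells, at least 589-fold higher. CEMIP, which takes part in breaking down hyaluronan, rose from 0.155 ± 0.176 to 24.1 ± 1.15 CPM (7.19, SE 0.37). RSPO3, an enhancer of WNT signalling, rose from 0.301 ± 0.207 to 19.7 ± 1.49 CPM (5.98, SE 0.39) and the urea transporter gene SLC14A2 from 0.710 ± 0.135 to 33.3 ± 2.04 CPM (5.55, SE 0.19). In all, 2639 genes changed in edgeR's quasi-likelihood test (adjusted p under 0.05, n = 2 per group), 1270 up and 1369 down, of which 494 changed at least 2-fold (253 up, 241 down). Leaving out 1 library gave 1388 genes without control library 1, 1499 without control library 2, 1548 without knockdown library 1 and 1533 without knockdown library 2.

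PLCL1 rose from a single control count to 5.29 ± 0.772 CPM (ratio 360.5, counting interval 64.3 to 14280), and KRT222 from 0.108 ± 0.153 to 4.40 ± 0.386 CPM (5.36, SE 0.68; fitted value 10.15 without control library 1). The U6 copies RNU6-5P, RNU6-3P, RNU6-2, RNU6-9 and RNU6-1 went from 2.85 ± 1.22 CPM to 0 (at least 58.6-fold lower), with the same uncertainty of near-identical copies. ATP6V1G2-DDX39B, a readthrough transcript that overlaps other genes, fell (−4.76, SE 1.19), a call lost without control library 2 (−3.56), knockdown library 1 (−4.25) or knockdown library 2 (−5.55). Further falls, named after their values were seen, were those of the pregnancy-specific glycoprotein genes PSG3 (control to knockdown ratio 14.1, counting interval 4.54 to 71.0) and PSG1 (−2.89, SE 0.41), which are near-identical paralogs and uncertain. Others were the adenylyl cyclase gene ADCY8 (−3.24, SE 0.32), LINC01502 (−2.89, SE 0.40) and the potassium channel gene KCNJ2 (−2.88, SE 0.22). Knockdown library 2 held the only knockdown counts of PSG3, which without it stood at 0.

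Some of the largest rises had changed neighbours. On chromosome 6, RNASET2, an RNase (2.25, SE 0.06), CEP43 (1.18, SE 0.08) and CCR6 rose side by side, while AFDN, the next gene, was not called (283.3 and 283.5 CPM). On chromosome 15, FAH, a tyrosine-degrading enzyme (1.23, SE 0.18), rose with CEMIP. On chromosome 8, PLEKHA2 (1.04, SE 0.07), TM2D2 (1.04, SE 0.06) and the metalloproteinase genes ADAM9 (1.45, SE 0.05) and ADAM32 (1.55, SE 0.17) rose.

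The type I interferon list rose, with 11 of 20 tested members up and 1 down (adjusted over the list alone, 13 up and 1 down; camera adjusted p = 5.78e-07). Its adjusted p = 0.0915 with an estimated correlation, the highest of 11 alternatives that ranged from 5.77e-13. That estimate was −0.0092, below the preset 0.01, so stronger correlation does not account for the higher value. ISG15, a ubiquitin-like modifier, rose (1.01, SE 0.09), as did MX1, a GTPase against viruses (3.06, SE 0.35), and IFI6 (1.04, SE 0.14). HERC5, the member that fell (−0.30, SE 0.08), lost its call without control library 2 (−0.18), knockdown library 1 (−0.33) or knockdown library 2 (−0.28). Antigen presentation genes had 5 rises and 1 fall among 12 (list alone, 6 and 1) and did not pass. B2M (0.40, SE 0.05) and HLA-E (0.43, SE 0.07), parts of class I molecules, rose. NLRC5, an activator of class I genes, fell (−0.55, SE 0.10).

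The mitosis and spindle checkpoint list fell, with 15 of 33 members down and 0 up (list alone, 18 and 0; camera adjusted p = 3.32e-05). Its adjusted p = 0.233 with an estimated correlation, the highest of 11 alternatives that ranged from 1.79e-05. MKI67 went from 333.2 ± 2.27 to 244.4 ± 13.3 CPM (−0.45, SE 0.06), and UBE2C from 39.1 ± 0.562 to 31.3 ± 1.15 CPM (−0.32, SE 0.07). The call of UBE2C was lost without control library 1 (−0.34), control library 2 (−0.31) or knockdown library 2 (−0.29). Condensin and cohesin genes had 6 falls and 0 rises among 25 (list alone, 6 and 0) and did not pass (camera adjusted p = 0.0592). Among them, NCAPH2, the target of the knockdown, fell. So did TOP2A (−0.22, SE 0.04), which untangles DNA in mitosis, a topoisomerase on the list and not a subunit of either complex. The call of TOP2A was lost without control library 1 (−0.21) or knockdown library 2 (−0.21).

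Cholesterol synthesis genes fell, 7 down and 0 up of 20 (list alone, 8 and 0; camera adjusted p = 0.00838; adjusted p = 0.233 with an estimated correlation, range 0.00272 to 0.233 over 11 alternatives). The falls included INSIG1 (−0.94, SE 0.07) and SQLE, squalene epoxidase (−0.74, SE 0.06). Mesenchymal genes fell, 4 down and 0 up of 15 (list alone, 4 and 1; camera adjusted p = 0.0178; adjusted p = 0.233 with an estimated correlation, range 0.00272 to 0.233 over 11 alternatives). FN1 went from 2285 ± 72.3 to 692.6 ± 9.35 CPM (−1.72, SE 0.08), and the tenascin gene TNC (−0.87, SE 0.07) and VIM (−0.85, SE 0.11) were lower as well. The call of the list was also lost without control library 1 (adjusted p = 0.0565).

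Unfolded protein and amino acid stress genes fell, 7 down and 3 up of 20 (list alone, 9 and 3; camera adjusted p = 0.0365; adjusted p = 0.240 with an estimated correlation, range 0.0282 to 0.240 over 11 alternatives). TRIB3 (−0.69, SE 0.07) and the amino acid transporter subunit gene SLC3A2 (−0.50, SE 0.05) fell, while VLDLR (1.26, SE 0.07) and XBP1, a transcription factor of the unfolded protein response (0.74, SE 0.06), rose. The call was lost with a replicate block (adjusted p = 0.0509) and without control library 1 (0.0691), control library 2 (0.0722) or knockdown library 2 (0.136). Fibroblast markers fell, 2 down and 0 up of 4 (list alone, 2 and 0; camera adjusted p = 0.0365; adjusted p = 0.233 with an estimated correlation, range 0.0148 to 0.233 over 10 alternatives). They were FBLN1 (−1.18, SE 0.07) and MFAP5 (−0.65, SE 0.07), which stood at 85.7 ± 1.15 and 81.2 ± 1.71 CPM in wild-type RMG1 cells. This call was lost without a filter (adjusted p = 0.176), in the 4 libraries alone (0.0776), and without control library 1 (0.0565) or knockdown library 2 (0.0838).

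Other lists held changed genes without passing. Ovarian clear cell markers had 6 rises and 6 falls among 14 (list alone, 6 and 6). TFPI2, a protease inhibitor (0.96, SE 0.05), and AMACR (0.71, SE 0.08) rose, and CDH6 fell (−1.02, SE 0.06). Collagens and matrix genes had 6 rises and 6 falls among 17 (list alone, 6 and 6). HSPG2, or perlecan, went from 6.03 ± 0.355 to 51.6 ± 0.237 CPM (3.10, SE 0.13), LAMB1 rose (0.90, SE 0.06) and LAMA3 fell (−1.51, SE 0.06). The NF-kB list had 4 rises and 8 falls among 19 (list alone, 5 and 9). IL6 (−2.05, SE 0.08) and BIRC3 (−1.38, SE 0.10) fell and CXCL8 rose (1.17, SE 0.15). Immediate early genes had 2 rises and 8 falls among 19 (list alone, 2 and 9). CCN1 (−0.86, SE 0.08) and KLF6 (−0.65, SE 0.06) fell and FOS rose (1.06, SE 0.15). NRF2 targets had 4 rises and 3 falls among 15 (list alone, 4 and 3). ME1 (0.48, SE 0.07) and AKR1C1 (0.77, SE 0.13) rose and SLC7A11 fell (−0.87, SE 0.10). SWI/SNF subunits had 2 rises and 4 falls among 26 (list alone, 3 and 6). BCL7B (−0.37, SE 0.07) and BCL7A (−0.39, SE 0.08) fell and SMARCA2 rose (0.52, SE 0.06). The call of BCL7A was lost without control library 2 (−0.35) or knockdown library 1 (−0.37).

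For the remaining lists in the knockdown, members up and down were 2 and 3 of 28 for G1/S and replication (list alone, 2 and 3), 1 and 4 of 16 for histones (1 and 5), 4 and 4 of 23 for p53 targets (4 and 5). They were 4 and 2 of 21 for epithelial genes (5 and 3) and 1 and 3 of 16 for YAP and TGF-beta targets (3 and 4). Counts were 4 and 2 of 19 for hypoxia and glycolysis (5 and 2), 2 and 1 of 16 for polycomb subunits (2 and 1) and 2 and 3 of 13 for genes reported as ARID1A-dependent (2 and 4). The last lists had 4 and 3 of 20 for DNA repair (5 and 4), 0 and 1 of 6 for leukocyte markers (1 and 1) and 0 and 1 of 27 for ribosomal proteins (0 and 0). The camera test, the median and the mean differed in sign for the p53, NRF2, DNA repair and ribosomal protein lists.

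The series title joins ARID1A to condensin II, so the responses to both perturbations were set against each other. They have no control library in common. Genes changed in both numbered 1518, of which 343 rose in both and 465 fell in both, against 213 and 243 for independent lists (one-sided Fisher's exact test across genes, p = 7.52e-22 and 7.34e-52). Another 357 rose in the knockout and fell in the knockdown and 353 did the reverse, against 230 and 225 (p = 5.80e-20 and 1.92e-20 in the same exact test). Thus 808 genes went the same way and 710 the opposite way: 53.2% of the shared changes had the same direction (exact binomial interval 50.7% to 55.8%; odds ratio 1.27, 1.03 to 1.56; two-sided Fisher's exact test across genes, p = 0.0231). Expected numbers among genes of similar expression were 251 and 325 for the same direction and 283 and 283 for the opposite ones. Genes are not independent replicates. With 1 library left out, the share in the same direction was 50.6% without control library 1 and 52.6% without control library 2. It was 51.7% without knockdown library 1 and 52.8% without knockdown library 2. On the ARID1A side it was 55.0% without wild-type library 1 and 52.4% without wild-type library 2. It was 53.7% without knockout library 1 and 53.1% without knockout library 2. A replicate block gave 672 and 624 (51.9%). Among genes changed at least 2-fold in both, 94 went the same way and 99 the opposite way.

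AQP1, a water channel, rose in both, from 0.0620 ± 0.0877 to 7.49 ± 0.236 CPM in the knockout (ratio 129.3, counting interval 44.0 to 629) and from 0.157 ± 0.134 to 2.34 ± 0.211 CPM in the knockdown. Wild-type library 1 held its only wild-type counts, and without it that group stood at 0. KRT222, absent in wild-type cells, was at 0.666 ± 0.166 CPM in knockout cells (at least 11.6-fold higher) and rose in the knockdown as well, with a fitted value of 10.15 without control library 1. RNU6-5P, RNU6-3P, RNU6-2 and RNU6-9 fell in both. RSPO3 fell from 1.12 ± 0.759 to 0.0405 ± 0.0203 CPM in the knockout (wild-type to knockout ratio 26.9, 8.76 to 134.6) and rose in the knockdown. SPINK1, a trypsin inhibitor, fell from 0.251 ± 0.00391 to 0.0137 ± 0.0194 CPM in the knockout (18.8, 2.82 to 797.4), where library 1 held its only count and without it the group stood at 0. It rose from 1.10 ± 0.412 to 7.61 ± 0.505 CPM in the knockdown. RNU6-1 rose in the knockout and fell in the knockdown.

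The other genes that the rule takes from both comparisons had few counts, and at least 1 call of each was lost on leaving out a library. Their CPM are given in the order wild type, knockout, control, knockdown, and adjusted p are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless DESeq2 is named. CELA3A (0, 0.188, 0, 1.67) rose in both, at least 3.23-fold and at least 38.0-fold. Its knockout call was lost on leaving out any 1 of the wild-type or knockout libraries (edgeR adjusted p 0.0642 to 0.0961) and in the 4 libraries alone (0.0551). AL359397.2 (0, 0.225, 0, 0.224) rose in both, at least 3.93-fold and at least 5.07-fold. Both calls were lost on leaving out any 1 library of the comparison (edgeR adjusted p 0.0511 to 0.152 in the knockout, 0.0688 to 0.207 in the knockdown) and with a replicate block (0.0584 and 0.0831). The knockout call was lost with DESeq2 too (adjusted p = 0.0584), and the knockdown call in the 4 libraries alone (edgeR adjusted p = 0.0527).

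The chemokine gene CXCL3 (0.0207, 0.400, 0, 0.192 CPM in the same order) rose in both, with a ratio of 20.8 in the knockout (counting interval 3.46 to 848) and at least 4.34-fold in the knockdown. Its knockout call was lost without wild-type library 2 (edgeR adjusted p = 0.104) or knockout library 2 (0.0842) and with DESeq2 (0.0646), and without wild-type library 1 the wild type stood at 0. Its knockdown call was lost on leaving out any 1 of the control or knockdown libraries (edgeR adjusted p 0.0780 to 0.144), with a replicate block (0.0803) and in the 4 libraries alone (0.0594). MYH16 (0.375, 0.0542, 0.442, 0.0161) fell in both, with a control to knockdown ratio of 27.6 (4.59 to 1127). Its knockout call was lost without wild-type library 2 (−1.87), knockout library 1 (−3.67) or knockout library 2 (−2.15). It was also lost with DESeq2 (adjusted p = 0.0838), and with edgeR in the 4 libraries alone (0.0668) and with a replicate block (0.0885). The knockdown call of MYH16 was lost without any 1 of the control or knockdown libraries (edgeR adjusted p 0.0552 to 0.120).

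CCL20, a ligand of CCR6 (0.109, 1.26, 0.601, 0.0158 CPM in the same order), rose in the knockout and fell in the knockdown (control to knockdown ratio 37.8, counting interval 6.41 to 1527). Its knockout value was 8.38 without wild-type library 2, and the call was lost without knockout library 1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0554). Its knockdown call was lost without control library 2 (edgeR adjusted p = 0.0509), knockdown library 1 (0.0514) or knockdown library 2 (0.0993). SLC17A3 (0.362, 3.10, 0.143, 0) rose in the knockout and fell at least 3.07-fold in the knockdown. The knockdown call was lost without control library 2 (edgeR adjusted p = 0.217), knockdown library 1 (0.148) or knockdown library 2 (0.152), in the 4 libraries alone (0.116) and with a replicate block (0.0549). AL109827.1 (1.61, 0.110, 0, 0.554) fell in the knockout and rose at least 12.7-fold in the knockdown. Its knockout call was lost without wild-type library 2 (−2.96) or knockout library 2 (−2.86) and with DESeq2 (adjusted p = 0.172), and the value was −8.68 without knockout library 1. Its knockdown call was lost without control library 1 (edgeR adjusted p = 0.157), control library 2 (0.163) or knockdown library 1 (0.237), with DESeq2 (0.0512) and with a replicate block (0.0554).

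Across all tested genes, Pearson's r between the log2 fold changes of both comparisons was 0.062 and Spearman's rho 0.0485. Over the genes changed in both, r was 0.206. With 1 library left out, r over all genes ran from 0.0282 (without knockout library 1) to 0.0835 (without control library 2). It was 0.0398 without knockdown library 1 and 0.017 with no filter on low counts.

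**Figure D4:**
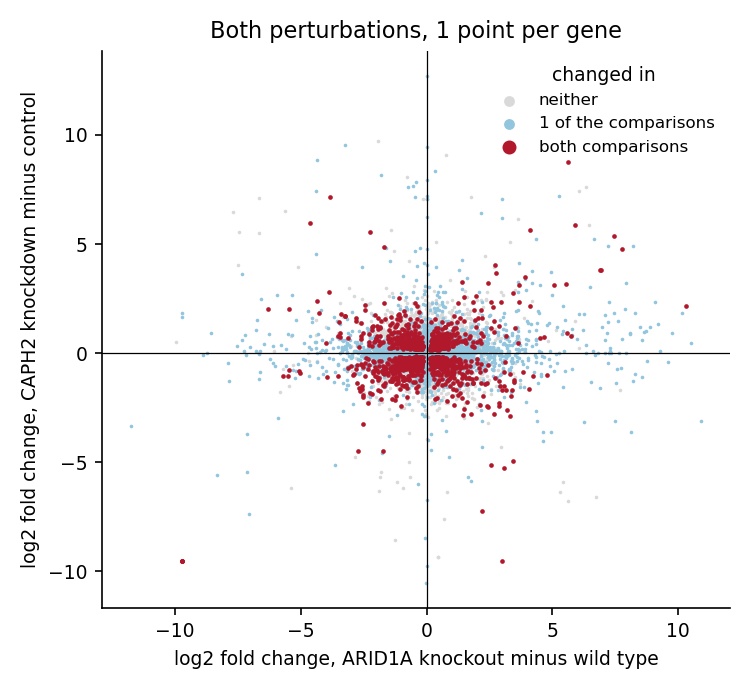
Log2 fold change in the CAPH2 knockdown (vertical axis) against that in the ARID1A knockout (horizontal axis), with 1 point for each of 16657 tested genes, coloured by whether it changed in neither, in 1 or in both comparisons. The 1518 genes changed in both fill all quadrants, with 808 in the same direction and 710 in opposite directions.

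The test of the difference between both effects asked which genes respond differently to ARID1A loss and to the CAPH2 knockdown. AKAP12, a scaffold protein gene, rose in the knockout (58.2 ± 4.78 to 652.8 ± 31.7 CPM) and fell in the knockdown (158.9 ± 1.67 to 64.6 ± 3.21 CPM), a difference of 4.79 on the log2 scale (SE 0.10). GJA1, or connexin 43, did the same (3.34 against −1.96; difference 5.30, SE 0.12), as did PLAU, the urokinase gene (2.14 against −2.37; difference 4.51, SE 0.11). CDH6 fell further in the knockout (−5.52 against −1.02; difference −4.50, SE 0.09), the long noncoding RNA NRAD1 was lower there (−4.24 against 0.06; difference −4.30, SE 0.10), and SGK1, a kinase gene, fell there and rose in the knockdown (−1.98 against 1.25; difference −3.22, SE 0.08). The effects differed for 4381 genes in edgeR's quasi-likelihood test, 2050 with the higher value in the knockout and 2331 with the lower, including all 710 genes called in opposite directions and 280 of the 808 called in the same one.

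Of the lists, NF-kB and inflammatory cytokines were higher in the knockout effect, with 12 of 19 members up and 1 down (list alone, 12 and 1; camera adjusted p = 1.16e-05; adjusted p = 0.135 with an estimated correlation). Mitotic genes were higher too, 18 up and 3 down of 33 (list alone, 22 and 4; camera adjusted p = 0.000968; adjusted p = 0.352 with an estimated correlation), and ovarian clear cell markers were lower, 9 down and 3 up of 14 (list alone, 10 and 3; camera adjusted p = 0.0012; adjusted p = 0.255 with an estimated correlation). The interferon list, which passed in the knockdown alone, had 7 members lower and 0 higher of 20 (list alone, 7 and 1) and did not pass the test of the difference (camera adjusted p = 0.0981). The camera test, the median and the mean differed in sign for the SWI/SNF, histone, mesenchymal, unfolded protein, NRF2, DNA repair and leukocyte lists.

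The comparison of shRNA control with wild-type cells shows how far RMG1 groups without either perturbation differ; the vector, the culture and the experiment cannot be told apart in it. THBS1, a matrix glycoprotein, was higher in shRNA control cells (11.3 ± 1.16 to 47.2 ± 0.421 CPM), as were VIM (5.71 ± 0.942 to 35.3 ± 4.17 CPM) and P4HA1, a collagen prolyl hydroxylase subunit (52.9 ± 1.51 to 118.3 ± 0.637 CPM), and CDH6 was lower (257.8 ± 0.621 to 89.9 ± 0.105 CPM). In edgeR's quasi-likelihood test 3205 genes differed, 1520 up and 1685 down, of which 454 differed at least 2-fold (296 up, 158 down). The number was 1592 without control library 1, 1645 without control library 2 and 1628 with a replicate block. Several genes named for a perturbation differed here in the same direction. For the knockout these included VIM, PAK3 (−4.39, SE 0.58) and COL4A1 (0.54, SE 0.06), and for the knockdown ADCY8 (−2.67, SE 0.21), LINC01502 (−2.72, SE 0.24) and PLEKHA2 (1.08, SE 0.07). The neighbours PSG3, PSG8 and PSG1, which fell in the knockdown, were lower here as well (median −1.90). CDH2 and PRSS35 stood at 0.531 ± 0.0801 and 0.163 ± 0.0326 CPM in shRNA control cells. This comparison shares its wild-type libraries with the knockout comparison and its control libraries with the knockdown comparison.

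Collagens and matrix genes were higher, 11 up and 0 down of 17 (list alone, 11 and 0; camera adjusted p = 7.85e-05; adjusted p = 0.196 with an estimated correlation), among them COL4A2 (0.85, SE 0.06) and LAMA3 (0.93, SE 0.06). Hypoxia and glycolysis genes were higher, 10 up and 1 down of 19 (list alone, 10 and 1; camera adjusted p = 0.00129; adjusted p = 0.196 with an estimated correlation), among them P4HA1 (1.16, SE 0.06) and NDRG1 (0.84, SE 0.07). NRF2 targets were lower, 9 down and 0 up of 15 (list alone, 9 and 1; camera adjusted p = 0.00174; adjusted p = 0.196 with an estimated correlation), with GCLM, a subunit of the enzyme that starts glutathione synthesis (−0.77, SE 0.07), and NQO1 (−0.50, SE 0.06). Targets of p53 were lower, 10 down and 2 up of 23 (list alone, 11 and 2; camera adjusted p = 0.0119; adjusted p = 0.196 with an estimated correlation), with CDKN1A, the cell cycle inhibitor p21 (−0.90, SE 0.09), and MDM2 (−0.39, SE 0.06), against a rise of GADD45A (0.57, SE 0.06). Genes of G1/S and replication (7 down and 1 up of 28; list alone, 8 and 1; camera adjusted p = 0.0119) and histones (5 down and 0 up of 16; list alone, 7 and 1; 0.016) were lower, with adjusted p = 0.201 with an estimated correlation for both. PCNA, the replication clamp, fell (−0.41, SE 0.05), and so did the linker histone gene H1-5 (−0.38, SE 0.06). DNA repair genes (9 down and 1 up of 20; list alone, 10 and 2; camera adjusted p = 0.0195), among them RAD51AP1 (−0.34, SE 0.07), and condensin and cohesin genes (9 down and 1 up of 25; list alone, 10 and 2; 0.0338), among them SMC4, a core subunit of condensin (−0.49, SE 0.05), were lower, with adjusted p = 0.196 with an estimated correlation for both. The interferon list, which rose in the knockdown, had 6 up and 1 down of 20 here and did not pass (camera adjusted p = 0.0725). Antigen presentation genes had 6 up and 1 down of 12 and did not pass either (camera adjusted p = 0.0713). The camera test, the median and the mean differed in sign for immediate early genes, clear cell markers and genes reported as ARID1A-dependent.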

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

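Alternatives covered scaling, filters on low counts, DESeq2, a fit to the 4 libraries of a comparison, a replicate block, a 2-fold minimum, an estimated correlation within lists and leaving out each library; leaving out regional windows and subtracting their medians were chosen after seeing the data. Of 109 values for counts of genes or lists and the correlation, 83 stayed the same and 26 moved. With a 2-fold minimum 1667 genes changed in the knockout, 494 in the knockdown and 94 the same way in both, fewer by construction. Leaving out 1 library, with the lone library assumed to vary like the others, gave 3977 to 5731 genes in the knockout, 1388 to 1548 in the knockdown, 3304 to 4849 for the difference, 1592 to 3469 between control groups and 434 to 1076 changed the same way in both. The correlation was 0.017 with no filter, 0.0912 with a stricter one and 0.0282 to 0.0835 with 1 library left out; the cause was not tested. With an estimated correlation 0 lists passed in the knockout and 0 in the knockdown, and with 1 library left out 2 passed in the knockout and 3 to 6 in the knockdown. The estimated correlation lay below the preset 0.01 for the NF-kB (−0.043), interferon (−0.0092), mesenchymal (−0.00068) and fibroblast (−0.10) lists. For these, stronger correlation does not account for the higher adjusted p. It lay above 0.01 for the mitosis (0.043), cholesterol (0.038), unfolded protein (0.017) and clear cell (0.014) lists. Whether correlation accounts for the higher adjusted p of those 4 lists was not tested. The clear cell estimate was close to the preset, yet the camera adjusted p of that list went from 0.00179 to 0.254. DESeq2 called 5010, 2337, 3803 and 2808 genes (knockout, knockdown, difference, control groups). Replicate numbers do not pair the samples; a block on them gave 5351, 2296, 3989 and 1628 genes, and deviations of libraries with the same number correlated between −0.0239 and 0.0296. Of 1244 values for named genes 1224 kept their sign and call, 17 lost the call (10 pairs of gene and comparison) and 3 reversed; with 1 library left out 696 of 760 kept both, 62 lost the call (21 such pairs) and 2 reversed. Those reversed were all of AFDN, near 0 and not called: −0.00223 with scaling without the 50 highest genes, −0.00256 with the stricter filter, −0.00505 with 4 libraries and −0.00818 to 0.00554 with 1 library left out. After subtraction of window medians ARID2 reversed to −0.0916. Leaving genes in shifted windows out moved no count of changed genes by over 1.5 times, but could hardly do so. It removed 1099 of 16657 tested genes, or 385 between control groups, and kept weakly expressed genes of the windows. It therefore cannot show that the calls are free of the regional shifts. For 5 values DESeq2 gave no adjusted p. With 1 count worth 0.0261 to 0.0413 CPM, depth limits what can be said of genes below that.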

Other observations

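Of the tests below, those of GC content and length and of weakly expressed genes were written before their results were seen, and all others after; the gene families were also chosen after seeing the data. S100A genes, which encode calcium-binding proteins, fell in the knockout, 8 of 11 down and 0 up (camera adjusted p over 37 families = 0.00159; adjusted p = 0.272 with an estimated correlation), with S100A14 going from 69.6 to 10.2 CPM and S100A9 falling too (log2 fold change −3.48). The keratin gene KRT23 went from 696.8 to 118.8 CPM. Pregnancy-specific glycoprotein genes rose in the knockout, 5 of 7 up and 0 down (camera adjusted p = 0.00653; adjusted p = 0.220 with an estimated correlation), among them PSG8 (1.93 to 32.8 CPM). In the knockdown 3 of 7 fell and 0 rose (camera adjusted p = 0.0299, and 0.372 with an estimated correlation). Without either perturbation the family differed too. In shRNA control against wild-type cells, 3 of 7 were lower and 1 was higher (median log2 fold change −1.48, camera adjusted p = 0.274). These paralogs are near-identical, so single values are uncertain.

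GBP2, an interferon-induced GTPase, fell in the knockout (99.8 to 47.9 CPM) and rose in the knockdown (100.4 to 314.7 CPM), and its family had 2 rises and 0 falls among 4 there (camera adjusted p = 0.0190; adjusted p = 0.372 with an estimated correlation). P4HA1 rose from 118.3 to 353.7 CPM in the knockdown and ST14, a membrane protease gene, from 62.4 to 186 CPM. Box C/D small nucleolar RNAs were higher in shRNA control than in wild-type cells, 24 of 78 up and 0 down (camera adjusted p = 9.07e-09; adjusted p = 0.385 with an estimated correlation). In the knockdown, against the same control libraries, 4 of 78 fell and 0 rose (camera adjusted p = 0.0212; adjusted p = 0.593 with an estimated correlation).

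Neighbouring genes shifted together in the ARID1A knockout, and 3 explanations were weighed. A GC content or transcript length trend is not enough, since 25 windows were beyond the bound after it was subtracted, 24 of them among the 29 before. A copy number or other inherited difference between the lines has the value it needs: 612 weakly expressed genes in the windows, not used to find them, shifted by 0.36 in the windows' direction (bootstrap interval 0.30 to 0.44). The bootstrap drew genes singly although neighbours shift together, so its interval is likely too narrow. Regulation of whole domains could shift these genes too, so the value does not separate these explanations. Regulation of whole domains after ARID1A loss stays open: 10 windows passed between the groups without ARID1A editing, and line and genotype coincide. The labels do not say whether the knockout cells are a clone or a pool. DNA was not measured. Some calls in these windows, including part of the fall of ARID1A, could therefore come from the line and not from ARID1A loss. Calls outside the windows could too, since line and genotype coincide for every gene of the comparison. Groups without either perturbation already differed in 3205 genes.

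Copies of U6 were called lower in both perturbations, and reads shared among near-identical copies could account for it. The sum over copies showed no fall beyond its spread, although 6 and 5 copies were called lower. Its log2 ratio was −0.13 (SE 0.47) in the knockout and −0.07 (SE 0.31) in the knockdown. With such SE a moderate fall of the sum cannot be excluded. The sum covers all 334 genes named as U6 copies that had counts, not only the copies called lower. RNU6-1 alone held 51.5% and 39.5% of U6 counts in the knockout libraries.

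Runs of 3 or more neighbouring genes rose in the CAPH2 knockdown, 5 runs against at most 2 in 1000 shuffled orders, but 3 runs fell there too (at most 2), and the knockout had 19 rising and 26 falling runs (at most 7 and 8). Reads counted for overlapping coding genes are not enough for PLEKHA2 to ADAM32 and FAH to ABHD17C. These were the 2 runs left among coding genes without overlap (at most 1 in shuffled orders). The run from FAH depends on ARNT2 (0.389 to 1.12 CPM), called near the threshold (edgeR quasi-likelihood adjusted p = 0.0493). Without that call the runs left would not exceed the shuffled orders, and runs were not searched again with a library left out. Overlap with noncoding genes was not examined. Overlapping reads stay open for CEMIP and the 3 runs not left, RNASET2 to CCR6, SLC14A2 and RALGPS2. An extra copy of the region is not enough for CEMIP, which exceeded the highest other coding member of its run by 5.57 (SE 0.42), or for CCR6, which exceeded RNASET2 by at least 6.95. It stays open for the other coding members, since RNASET2 exceeded CEP43 by 1.07 (SE 0.10), FAH to ABHD17C spanned 0.39 (SE 0.28) and PLEKHA2 to ADAM32 spanned 0.50 (SE 0.18). Local activation, such as next to an inserted vector, stays open: AFDN, beside CCR6, stood at 0.00098, and insertion sites and condensin II occupancy are not given in the sources used here.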
